A study of Mus musculus with 2 samples.

How the data were processed

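Spatial gene expression was measured in 2 formalin-fixed, paraffin-embedded sections of mouse skin tumours, 1 from a control animal and 1 from an animal treated with NP137, a monoclonal antibody against netrin-1. All deposited samples were used. The animals carried a tamoxifen-inducible Cre under the Lgr5 promoter that removes Trp53 in hair follicle stem cells. Libraries were made with the 10x Genomics Visium kit on probe-hybridised tissue, per the labels' protocols. The design text names the mouse transcriptome probe set but describes the probes as human-specific; the gene identifiers in the files are all of mouse genes. A Visium spot is a small round area of tissue that can hold several cells of different types.

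The deposited values are counts of unique molecular identifiers (UMIs) per gene and spot, raw whole numbers with no normalization by the authors. Per the submitters' processing notes the tables were made with Space Ranger and the mm10 build. The program's version, the probe filter and the way spots under tissue were chosen are not given in the sources used here. The other deposited values that were used are the array row and column of each spot, whose unit is the array's own grid, per the authors' position files. Image scale factors were not used here, and no image was analysed here.

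Each table lists 19465 genes, of which 11 symbols occur more than once. Genes were named by the symbols in the files. Positions came from a RefSeq gene table for GRCm38.p6, the assembly that mm10 stands for. Of the 19465 symbols, 19106 matched that table, and all 159 named genes of the whole-section comparison were located. Only spots marked as under tissue were in the tables, and no spot was removed from sums. No doublet caller was run, and no cell-type deconvolution was made, so shares are shares of spots.

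Each sample was 1 section, so no difference below has a replicate check, and no p-value, standard error or count of changed genes was computed. Counts were summed over all spots of a section and divided by the section's total, and given as CPM (the standard counts-per-total unit). Levels have exact 95% Poisson intervals, ratios have exact 95% intervals from the conditional binomial, and shares have exact 95% Clopper-Pearson intervals. All of them cover counting error only and leave out differences between animals, tumours and sections. When genes were ranked by ratio, a count under 3 in a section was set to 3, which gives a lower bound of the fold. For list medians a count of 0 was set to 0.5 unless the bound is named. A gene was counted as higher at a ratio (NP137 / control) of at least 1.5, as lower at the inverse of that ratio or less, and otherwise as between, which is a rule of size and not a test.

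Before the data were examined, 33 gene lists were fixed, among them epithelial, mesenchymal, EMT transcription factor (EMT is epithelial-mesenchymal transition), netrin and cell type lists, together with the design and its alternatives. A list's value is the median log2 ratio of its members with at least 20 counts over both sections. It was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and the percentile describes these 2 libraries. The named genes are the 12 with the highest and the 12 with the lowest ratio among genes with at least 50 CPM in the higher section, all measured members of the EMT surface protein, netrin, model gene and sex-linked lists, up to 2 members at each end of every other list among those with at least 50 counts, the 10 genes with the highest Moran's I in each section, and the 5 leading genes of each region. Vim and Krt14 are named because the fixed design measures them with Epcam. Not every gene that meets this rule is printed. Genes named outside this rule are said to be so.

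The mesenchymal share is the UMIs of the mesenchymal list divided by those of the mesenchymal and epithelial lists. Per spot it was computed where at least 20 such UMIs were found. For measures per spot, each spot was thinned to 1300 UMIs, the 10th percentile of the NP137 section, and shallower spots were left out. The correlation of the epithelial and mesenchymal sums across spots (Spearman's rho of 1 thinning, with its range over 20 thinnings) was set beside that of 1000 pairs of matched random lists. Moran's I measures how alike neighbouring spots are, with up to 6 neighbours per spot and genes with at least 500 counts. Regions came from joint Leiden clustering of both sections at resolution 0.5, on 30 principal components of 2000 variable genes, without the 64 measured genes of the EMT lists and without integration.

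The control section held 34595197 UMIs in 1426 spots and the NP137 section 17003635 UMIs in 1166 spots. At these depths 3 counts correspond to 0.0867 CPM and 0.176 CPM. Scaling by the trimmed mean of M values (TMM, edgeR 4.0.16) shifted every log2 ratio by 0.04, and a median-of-ratios scaling by 0.05. The median log2 ratio of the 14195 genes with at least 20 counts was -0.12.

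Alternatives were the 2 scalings, a minimum of 200 counts per gene, no minimum count, the mean of per-spot CPM, a minimum of 5000 UMIs per spot, other thinning depths, other forms of the share and the correlation, and other cluster settings. After the data were seen, 2 more were added. One left out the NP137 spots of regions 5, 7, 9 and 11, whose leading genes were those of muscle, fat, plasma cells and cornified epidermis, and the other thinned the spots before summing. The first kept the control spots of regions 7 and 9.

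The steps were tested on simulated data. In counts drawn for 14195 genes with 200 changed genes, 96% of 25 genes set 2-fold higher and 100% of 25 set 4-fold higher passed the size rule, and 2.82% of 13995 unchanged genes did. The 95% intervals held the true ratio for 95.4% of the unchanged genes, and for 88% of genes set 2-fold higher or 2-fold lower. Of simulated lists without change, 94% fell within the central 95% of random lists. These counts were drawn with counting error only, around 1 profile shared by both sections. The rates therefore check the code and are not error rates for 2 sections of different animals and tissue. Simulated opposite gradients gave a rho of -0.96, and 2 lists without a gradient gave -0.10. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2, matplotlib 3.10.9 and R 4.3.3.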

Results

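The data were 2 sections of skin squamous cell carcinoma, 1 from a control mouse and 1 from a mouse given NP137 at 10 mg/kg every 2 days from 4 weeks after tamoxifen until death. Tamoxifen was given as 4 daily injections of 2.5 mg from 28 days of age, and tumours were seen 7 to 9 weeks later. The control section had 1426 spots with a median of 20213.5 UMIs and 6621 genes per spot. The NP137 section had 1166 spots with a median of 12286 UMIs and 4926 genes, and 52 of its spots held under 500 UMIs. Each group was a single section, so the values below compare 2 sections, not 2 conditions.

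Ntn1, which encodes netrin-1 (ENSMUSG00000020902, GRCm38 chromosome 11, 68209364 to 68386826), was measured at 116 CPM (95% interval 112 to 119) in the control section and at 59.6 CPM (56.0 to 63.4) in the NP137 section. It was 1.94-fold lower in the NP137 section (1.81 to 2.08). The dependence receptor Unc5b (chromosome 10, 60762594 to 60831581) was 2.35-fold lower, at 126 against 53.7 CPM, and Unc5a was 22.5-fold lower, at 18.6 against 0.823 CPM. The receptor Neo1 was alike, at 79.0 and 81.5 CPM. Dcc and Dscam were lower, with 42 against 2 and 73 against 3 counts, while Ntn3 (1.36 against 2.12 CPM) and Unc5c (1.59 against 2.41 CPM) were higher by the size rule, with intervals that include no difference.

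Among the 12 measured genes of the netrin list, 5 were higher, 5 lower and 2 between. The other higher ones were Draxin (1.68 against 9.06 CPM), Ntng2 (7.92 against 24.6 CPM) and Adora2b (9.77 against 16.5 CPM), and Ntn4 was at 40.5 and 46.5 CPM. The list's median log2 ratio of 0.12 lay at percentile 71.3 among random lists, so the list as a whole did not stand apart. Transcript levels do not show how much netrin-1 protein was bound or free.

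The epithelial list of adhesion, junction and keratin genes was higher in the NP137 section, with a median log2 ratio of 2.98 (2.94 to 3.002), above all 10000 random lists. Of its 31 measured members 26 were higher, 0 lower and 5 between. Epcam, an epithelial adhesion molecule (ENSMUSG00000045394, chromosome 17, 87635979 to 87651127), was at 14.2 CPM in the control and 566 CPM in the NP137 section, 39.9-fold higher (36.5 to 43.8). Cldn7, a tight junction protein, was 35.4-fold higher from 0.636 CPM. Krt14, a keratin of basal keratinocytes, was at 992 and 7799 CPM. The lowest ratios of the list were those of Sfn (5.20 and 4.41 CPM) and Itga6 (209 and 191 CPM).

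The mesenchymal list did not move as a group. Its median log2 ratio was -0.17 (-0.24 to -0.15), at percentile 48.1, with 5 of 22 members higher, 6 lower and 11 between. Vim, an intermediate filament of mesenchymal cells, was 1.82-fold lower, at 3030 against 1661 CPM. Cdh2, which encodes N-cadherin, was 4.84-fold lower, while the matrix glycoprotein Tnc was 2.69-fold higher and Cdh11 2.33-fold higher. Of 9 measured EMT transcription factors 5 were lower, 1 higher and 3 between, with a median of -0.61 at percentile 2.59. Foxc2 (52.8 against 10.1 CPM) and Snai1 (292 against 94.5 CPM) were lowest, Aebp1 was at 233 and 262 CPM, and Snai2, which basal keratinocytes also express, was 4.22-fold higher at 27.1 against 114 CPM.

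Among the surface proteins used to sort EMT states, Vcam1 (89.9 against 49.6 CPM) and Itgb3 (61.4 against 25.4 CPM) were lower. Itgav was at 259 and 232 CPM, Itgb1 at 346 and 306 CPM and Itgb5 at 278 and 303 CPM. With Epcam the list of 6 had a median of -0.17, at percentile 49.4, and of 0.043 without the NP137 spots of regions 5, 7, 9 and 11. The TGF-beta list had a median of -0.35 at percentile 14.1, with 6 of 18 members lower and 4 higher. Tgfbr1 was 2.50-fold lower, at 202 against 80.6 CPM, while Thbs1 was 2.12-fold higher and Itgb6 22.5-fold higher.

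Markers of fat, skeletal muscle and cornifying keratinocytes differed in the same direction as the epithelial genes. No image was analysed, so whether these tissues lay in or beside the tumour is not known. The median log2 ratio was 4.31 for adipocyte genes, or 4.03 with the gene at 0 counts set to its bound, 2.998 for skeletal muscle genes and 4.20 for cornifying keratinocyte genes. Without the NP137 spots of regions 5, 7, 9 and 11, left out after their leading genes were seen, the skeletal muscle median was 0.13, the keratinocyte differentiation median 1.76 and the epithelial median 2.59, with 27 epithelial members higher and 0 lower.

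**Figure D1:**
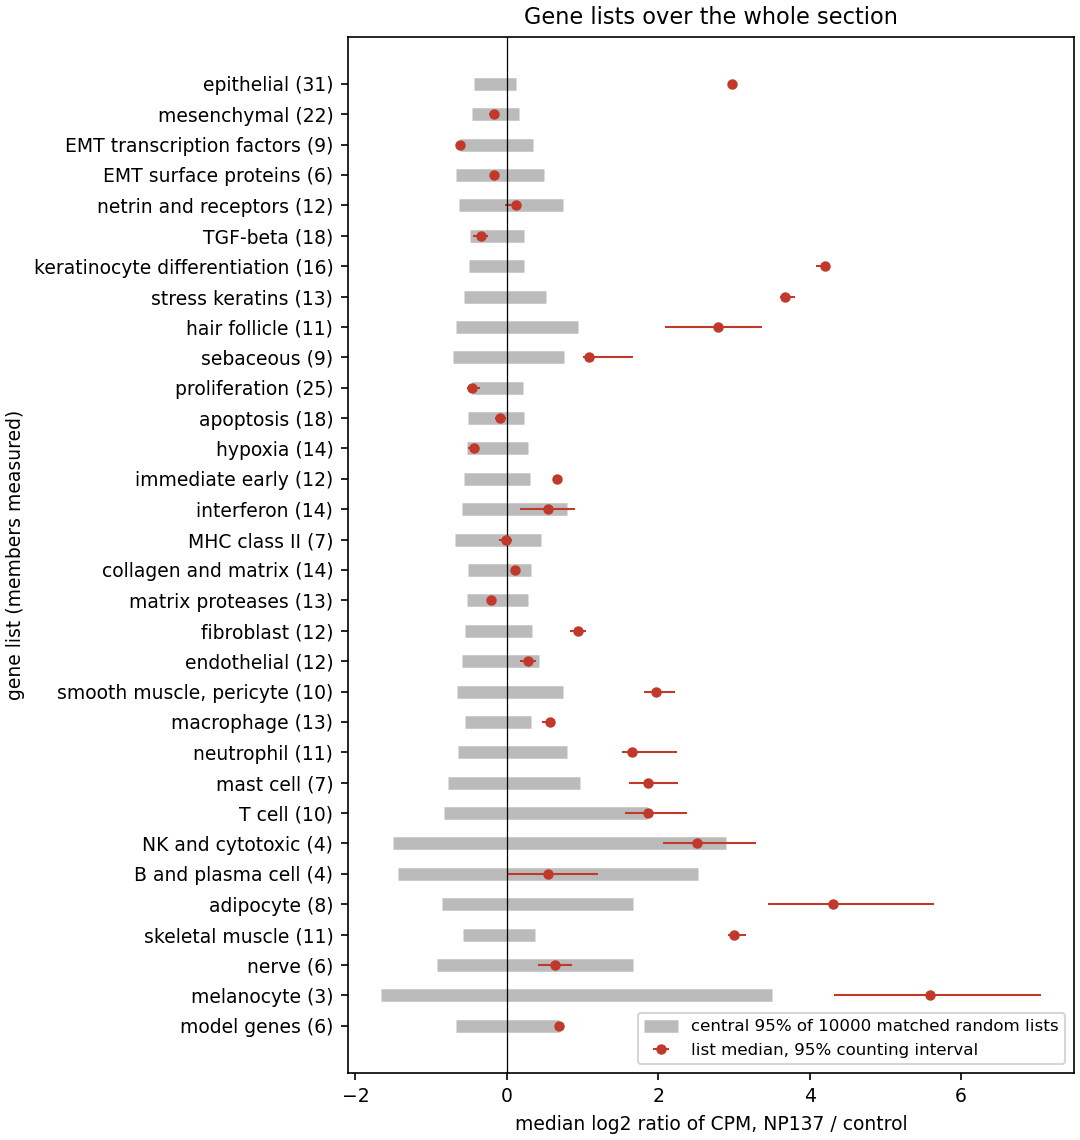
Median log2 ratio of CPM (NP137 / control) for 32 of the 33 gene lists, the sex-linked list being left out, with the number of measured members in brackets. Points are medians with 95% counting intervals, and grey bars are the central 95% of 10000 matched random lists; the epithelial list lies at 2.98 and the mesenchymal list at -0.17.

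The mesenchymal share of EMT-list UMIs was 81.7% (81.6 to 81.8) in the control and 42.2% (42.1 to 42.4) in the NP137 section, a difference of -39.4 percentage points. The summed mesenchymal list was at 14096 and 12831 CPM and the summed epithelial list at 3162 and 17549 CPM. The lower share thus came mostly from the higher epithelial sum. Without keratin genes the shares were 88.3% and 62.5%. Over spots, the median share was 86.2% in the control (quartiles 81.6% and 89.0%) and 43.3% in the NP137 section (quartiles 16.1% and 84.7%). In the control, 1278 of 1423 spots (89.8%, 88.1 to 91.3) had a share of at least 75%, and 12 (0.843%) had a share under 25%. In the NP137 section these were 355 of 1095 spots (32.4%, 29.7 to 35.3) and 384 spots (35.1%, 32.2 to 38.0). The NP137 section therefore held spots over the whole range of the share, and the control section mostly its upper end. Within 5 percentage points of the 75% bound lay 178 control and 78 NP137 spots.

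**Figure D2:**
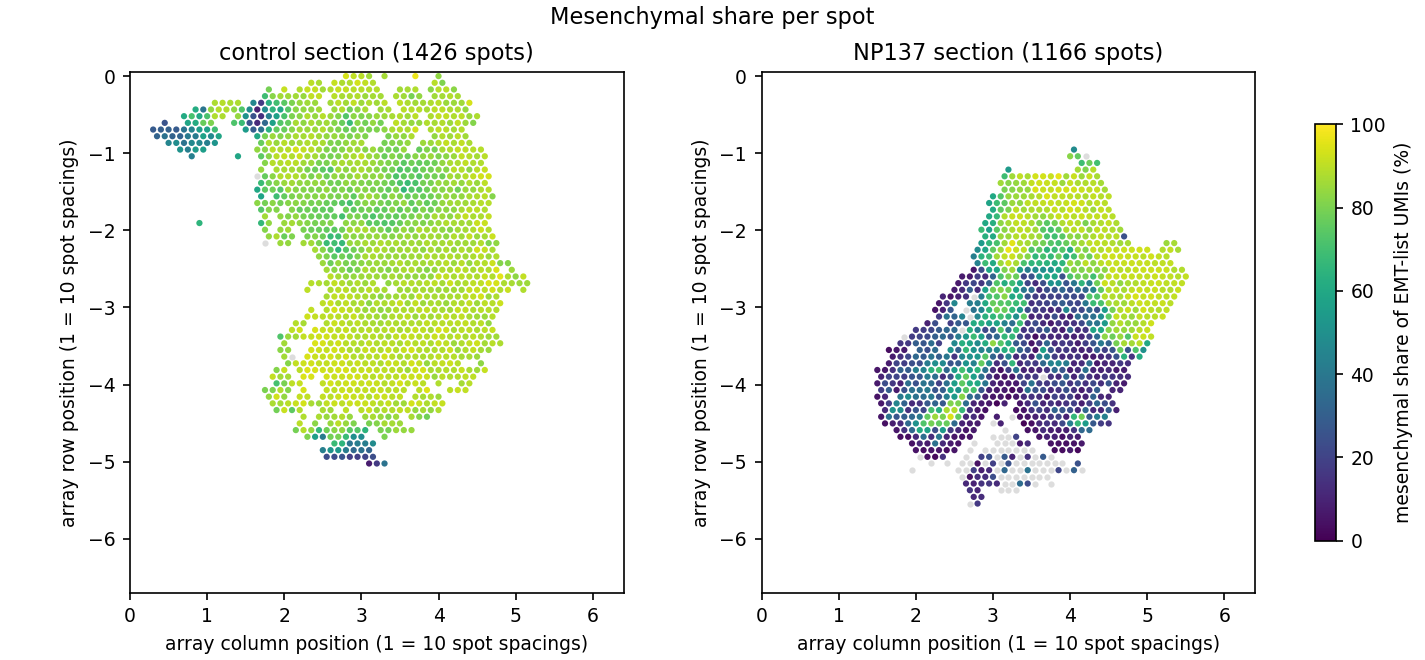
Each dot is a spot at its array position, coloured by the mesenchymal share of EMT-list UMIs from 0 to 100%; grey spots had under 20 such UMIs. The control section (1426 spots) is mostly at high shares, and the NP137 section (1166 spots) has a mesenchymal-rich part at the upper right and mostly lower shares elsewhere.

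Epithelial and mesenchymal list sums were inversely related across spots of the NP137 section, and after thinning no such relation was seen in the control. At equal depth, Spearman's rho of the 2 list sums across 1049 NP137 spots was -0.74, below all 1000 pairs of random lists, whose central 95% ran from -0.28 to 0.30. Across 1423 control spots rho was 0.01, within the random range of -0.07 to 0.14. Over 20 thinnings rho ran from -0.75 to -0.72 in the NP137 section and from -0.03 to 0.05 in the control. Spots are not replicates. Without thinning the control value was 0.21, and with sums of z-scores it was 0.23. The epithelial list summed to 3162 CPM in the control and 17549 CPM in the NP137 section. Thinning therefore left fewer of its UMIs per control spot, and counting noise may hide a relation there.

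Spots with UMIs of both Epcam and Vim made up 2.32% (1.60 to 3.24) of control and 18.9% (16.5 to 21.4) of NP137 spots after thinning to 1300 UMIs, which left out 3 control and 117 NP137 spots. Independence of the genes would give 2.46% and 27.1%. Epcam alone was found in 2.53% of control and 38.4% of NP137 spots, and Vim in 97.3% and 70.6%. The share difference was 16.6 percentage points (14.1 to 19.2). Without thinning the shares were 16.3% and 60.5%, a difference of 44.1 points. With Krt14 in place of Epcam the shares were 53.9% and 54.6%, a difference of 0.72 points (-3.31 to 4.75). A spot with both genes may hold cells of each kind, so these shares do not count cells in a mixed state.

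Neighbouring spots were most alike for different genes in the 2 sections. In the control, Moran's I was highest for Acp5 (0.92), Ctsk (0.92), Mmp9 (0.91), Spp1 (0.90) and S100a6 (0.89), followed by Cxcl14, Col5a2, Igfbp7, Mmp13 and Ecm1. In the NP137 section it was highest for the muscle genes Myh4 (0.87), Ttn, Tnnt3, Tnnc2, Acta1, Mylpf, Myl1 and Ckm and for Krtdap (0.86) and Krt14 (0.85).

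Clustering gave 11 regions, and none held 50 spots of both sections, so the fixed comparison of the mesenchymal list within shared regions has no value. With 1 section per group, a region found in 1 section may be that section and not a tissue type. Control spots lay mostly in region 1 (36.6%, led by Megf10, St8sia6, Fmo2, Spock2 and St8sia2), region 2 (28.1%, led by Car9, S100b, Klhl1, Timp3 and Igf2), region 6 (14.4%, led by Tnfsf11, Aldh3a1, Mmrn2, Tmem163 and Ptprn), region 8 (171 spots, led by Angptl7, Dync1i1, Mycn, Ppp1r9a and Nalcn) and region 10 (4.35%, led by Il6, Il11, Csf3, Ptgs2 and Cxcl1). NP137 spots lay in region 3 (29.3%, led by Gpr149, Gzmf, Spon2, Cnr1 and Gzmc), region 4 (21.4%, led by Psca, Gm9573, Ltf, Cldn3 and Gabrp), region 5 (20.7%, led by Cfd, Igkc, Jchain, Igha and Ighj1), region 7 (15.1%, led by Adgrg7, Serpinb3a, Oas1f, Krt1 and Them5), region 9 (8.49%, led by Sprr1b, Gjb6, Gjb2, Sprr2i and Igfbp2) and region 11 (4.55%, led by Myh4, Pvalb, Myom2, Fitm1 and Mybpc2). Regions 4, 7 and 9 also held 9, 24 and 31 control spots. Leading genes were taken from the spots of both sections together. In region 9 the control spots gave 206694 UMIs and the NP137 spots 73215, so its leading genes describe mostly control spots.

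**Figure D3:**
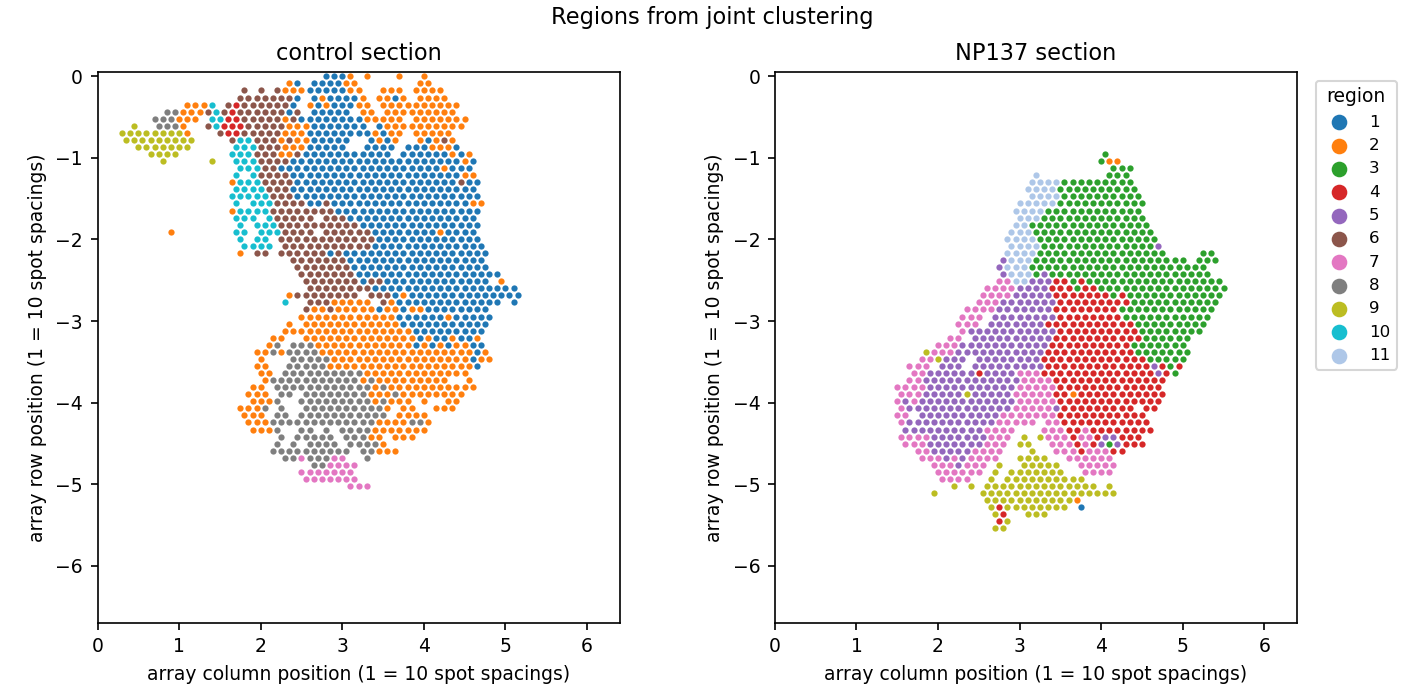
Spots of the control and NP137 sections at their array positions, coloured by the 11 regions from joint clustering without the EMT-list genes. Regions 1, 2, 6, 8 and 10 lie almost wholly in the control section, and regions 3, 5 and 11 wholly in the NP137 section.

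The EMT-list genes differed between the NP137 regions. They were left out of the clustering, but other keratinocyte and matrix genes were not, so this difference is not independent of how the regions were made. Region 3 had a mesenchymal share of 86.6%, with Vim at 3007 CPM (2966 to 3048), Epcam at 36.1 CPM (31.8 to 40.9) and Krt14 at 780 CPM. Region 4 had a share of 21.3%, with Vim at 611 CPM, Epcam at 1253 CPM (1224 to 1283) and Krt14 at 16317 CPM. Region 7 had the lowest share, 9.73%, and region 5 had 51.4%. The large control regions 1, 2, 6 and 8 had shares of 83.6%, 88.1%, 80.2% and 87.8%, with Epcam between 3.85 and 11.7 CPM.

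Ntn1 varied more across the regions of the control section than between the whole sections. It was at 283 CPM (270 to 297) in region 8 and 130 CPM (122 to 138) in region 2, against 55.4 CPM in region 1 and 53.9 CPM in region 6. The control spots of region 9, with Sprr1b and Gjb6 among its leading genes, had 266 CPM (200 to 346), and those of region 7, with Krt1 among them, 152 CPM (123 to 187). In the NP137 section it was at 130 CPM (115 to 148) in region 5, 77.1 CPM (70.7 to 84.0) in region 3 and 25.9 CPM (21.8 to 30.5) in region 4. The NP137 spots of region 7 had 35.6 CPM (28.3 to 44.2) of Ntn1 and those of region 11 had 29.6 CPM (12.8 to 58.3). Those of region 9 had 27.3 CPM (3.31 to 98.7), from 2 counts. Unc5b was at 138 CPM in region 1, 140 CPM in region 2 and 149 CPM in region 6, but at 70.4 CPM (63.9 to 77.4) in region 8, where Ntn1 was high. In the NP137 spots Unc5b was at 72.5 CPM in region 3 and 49.8 CPM in region 4.

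**Figure D4:**
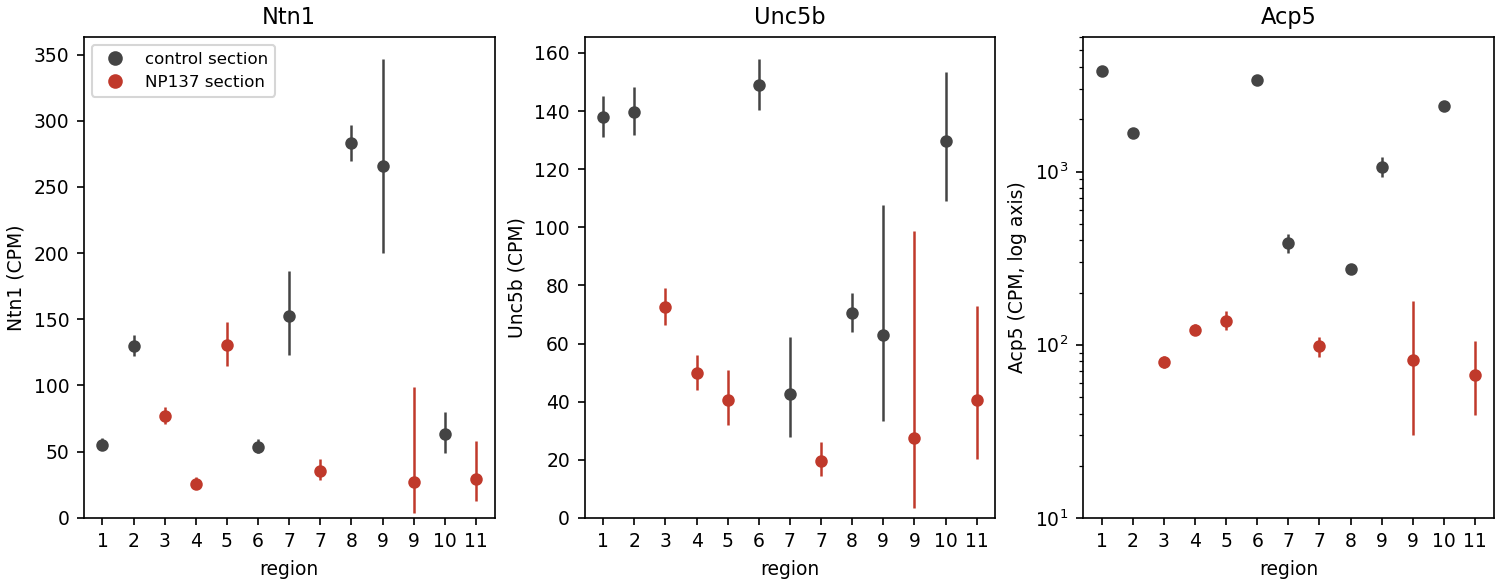
CPM of Ntn1, Unc5b and Acp5 (log axis for Acp5) by region for regions with at least 20 spots of a section, with exact 95% Poisson intervals; grey points are control and red points NP137 spots. Ntn1 is highest in region 8 of the control (283 CPM), where Unc5b is at 70.4 CPM.

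The 12 genes with the highest ratios were H2-D1, a classical MHC class I gene (1 against 3034 counts, ratio 6173, interval 1107 to 243900), the secreted proteins Wfdc18 and Sostdc1, the epidermal lipoxygenases Alox8 and Alox12e, the defensin Defb3, the iron-binding protein Ltf (3.84 against 639 CPM), Krt77, Myh4, Psca (4.25 against 373 CPM), Rnase2b and Gpx2. The 12 with the lowest ratios were Eif2s3y, Tmpo (265 against 7.88 CPM), Slc9b2, Ckb, the osteoclast differentiation factor Tnfsf11 (126 against 5.12 CPM), the acid phosphatase Acp5 (2468 against 102 CPM, 24.1-fold lower), Igf2, Angptl7, Alx4, Mt3, Il11 and Matn4.

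The animals differed in sex. The Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty had 4295, 1703, 1108 and 1254 counts in the control and 0 in the NP137 section, where the exact upper limit at 0 counts is 0.217 CPM. With 0 set to 3 counts Eif2s3y was at least 704-fold lower, and by the exact interval at least 572-fold, and the list's median log2 ratio was -7.90 with all 4 genes at their bound. Of the model genes, Trp53 was at 24.1 and 29.3 CPM, Nras at 227 and 184 CPM, Hras at 177 and 369 CPM and Cdkn2a at 290 and 582 CPM. Lgr5, whose promoter drives the recombinase, had 3 and 32 counts. The list had a median of 0.69 at percentile 97.4. Probe counts do not tell the altered alleles from the intact ones.

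Epidermal lists were higher in the NP137 section. All 16 keratinocyte differentiation genes were higher, from Tgm1 (19.3 against 108 CPM) and Lor (61.4 against 612 CPM) to Flg2 (23.2-fold) and Casp14 (46.7-fold). All 13 stress keratin and alarm genes were higher, with a median of 3.68, among them Sprr1b (4.49-fold) and Sprr2d (34.7-fold), and Il24 and Sprr3 at low counts. The hair follicle list had a median of 2.79, with 8 of 11 members higher, among them Krt15 (13.7-fold) and Krt75, and with the follicle transcription factor Lhx2 (72.2 against 7.76 CPM) and Tcf7l1 (53.9 against 33.5 CPM) lower. The hair_follicle list, whole section, had a median of 0.25 with a minimum of 200 counts per gene, 1.92 with no minimum, 3.85 with the mean of per-spot CPM and 1.22 without the NP137 spots of regions 5, 7, 9 and 11. The sebaceous list had a median of 1.09, with Far2 58.0-fold and Awat1 61.0-fold higher and Mgst1 and Soat1 between, and a sebaceous list median of 0.52 without those regions and 2.13 with no minimum count. Melanocyte genes had a median of 5.59 over 3 members at low counts, with Dct at 5 and 204, Tyrp1 at 3 and 71 and Pmel at 13 and 42 counts. The melanocyte list, whole section, had a median of 3.06 without those regions and 6.37 with the mean of per-spot CPM. With a minimum of 200 counts Dct alone was left, at 6.38.

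Among lists of immune cells, the neutrophil list had a median of 1.66 at percentile 99.8, with 10 of 11 members higher. S100a9 (85.1 against 2484 CPM) and S100a8 (96.0 against 1436 CPM), which keratinocytes under stress also express, led it, and Il1b and Ngp were 2.30-fold and 1.52-fold higher. The neutrophil list, whole section, had a median of 2.51 with a minimum of 200 counts. The macrophage list had a median of 0.58 at percentile 99.8, with 6 of 13 higher and 2 lower. The arginase Arg1 was 18.3-fold and Cd163 3.63-fold higher, while Spp1 (2799 against 1491 CPM) and Cd68 (284 against 165 CPM) were lower. Of the 36572 NP137 counts of Arg1, 817 lay in spots with a mesenchymal share of at least 75%. There Arg1 was at 93.8 CPM in the control and 121 CPM in the NP137 section, so its rise lay mostly in other spots. Which cells gave the Arg1 counts was not tested. Mast cell genes had a median of 1.87, with Fcer1a 6.55-fold, Cpa3 (3.84 against 19.2 CPM) and Mcpt4 2.61-fold higher and Kit at 15.9 and 19.3 CPM.

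Lymphocyte lists rested on few counts. The T cell list had a median of 1.87, with Cd3e at 15 and 109, Cd3g at 12 and 104, Il2rb at 32 and 18 and Cd4 at 226 and 73 counts. Its value was -0.61 with a minimum of 200 counts per gene, where Cd4 alone was left. Its median was 1.06 without the NP137 spots of regions 5, 7, 9 and 11. The natural killer and cytotoxic list had a median of 2.51, with Prf1 at 30 and 86 and Gzmb at 29 and 59 counts. The B and plasma cell list had a median of 0.55, with Jchain at 31 and 423 and Cd79b at 20 and 33 counts, and the b_plasma list, whole section, had 4.795 with a minimum of 200 counts, where Jchain alone was left, and 1.58 with the mean of per-spot CPM. MHC class II genes had a median of -0.02 with opposite members, H2-Aa 4.39-fold higher and H2-Eb1 2.13-fold lower, and H2-Ab1 and H2-DMa between. The mhc2 list, whole section, had 0.44 with the mean of per-spot CPM and -0.30 without those regions, so its direction depended on the setting. The interferon list had a median of 0.55 at percentile 93.1, from Irf7 (6.50-fold) and Usp18 (3.97-fold) to Irf1 between and Cxcl10 (188 against 58 counts) lower. The interferon list, whole section, had a median of 0.013 with a minimum of 200 counts per gene and of 0.12 without the NP137 spots of regions 5, 7, 9 and 11, so its higher median rested on few counts and on those regions.

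Stromal lists were mixed. The fibroblast list had a median of 0.94, above 9999 of the 10000 random lists, with Clec3b 59.2-fold and Pi16 14.2-fold higher and Cxcl12 (366 against 166 CPM) and Pdgfrb (212 against 122 CPM) lower. The collagen and matrix list, with Ctsk and Postn among its 14 genes, had a median of 0.11, with Col3a1 3.91-fold and Col12a1 2.77-fold higher, Col5a2 1.62-fold lower and the protease Ctsk 10.8-fold lower. Matrix proteases and inhibitors had a median of -0.21, with Mmp12 12.9-fold and Mmp11 2.40-fold higher, Mmp9 7.10-fold lower and Timp3 lower at 934 against 311 CPM. The endothelial list had a median of 0.28, with Tek and Plvap higher and 10 of 12 members between, Egfl7 and Robo4 among them. The smooth muscle and pericyte list had a median of 1.97, with Cnn1 and Lmod1 highest at 54 and 50 NP137 counts and Kcnj8 and Mustn1 between, and a median of 1.32 without the NP137 spots of regions 5, 7, 9 and 11. The nerve list had a median of 0.63, and -0.88 with a minimum of 200 counts per gene, with S100b at 1014 and 110 and Prx at 437 and 117 counts. The muscle and fat lists ran from Tnni2 (1.44-fold) and Myh2 to Atp2a1 (21.4-fold) and Myh4, and from Lipe (1.83-fold) and Pparg to Plin4 and Cfd (2 against 169 counts). The adipocyte list, whole section, had a median of 1.82 with a minimum of 200 counts, 6.69 with the mean of per-spot CPM, 3.27 in spots with at least 5000 UMIs and 1.85 without those regions. The skeletal_muscle list, whole section, had 4.16 with the mean of per-spot CPM and 2.35 in spots with at least 5000 UMIs.

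Of the cell state lists, the cell cycle list had a median of -0.46 at percentile 2.56, with 8 of 25 members lower, Mcm2 (156 against 67.9 CPM) and Mcm4 the lowest, and Ccnb2 (1.57-fold) higher and Plk1 between. Without the NP137 spots of regions 5, 7, 9 and 11 its median was -0.22, with 6 members lower. The hypoxia list had a median of -0.44 at percentile 7.39, with Car9 (64.6 against 13.8 CPM) and P4ha1 (286 against 133 CPM) lowest and Egln3 (2.03-fold) and Pgk1 (1.62-fold) higher. Apoptosis genes had a median of -0.09, with Tnfrsf10b 2.05-fold lower, and with the cell cycle inhibitor Cdkn1a 2.73-fold and Pmaip1 2.41-fold higher. Immediate early and heat shock genes had a median of 0.66 at percentile 99.9, led by Hspa1a (5.45-fold) and Hspa1b (4.20-fold), with Ier3 lower and Ier2 between. That median was 0.21 without the NP137 spots of regions 5, 7, 9 and 11.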

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

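Leaving out the NP137 spots of regions 5, 7, 9 and 11 and thinning before summing were chosen after the data were seen; the other alternatives were fixed beforehand. The median log2 ratio of the epithelial list was 3.02 with TMM, 3.03 with median-of-ratios scaling, 2.59 without those regions and 2.94 after thinning. For the mesenchymal list the values in the same order were -0.13, -0.12, -0.016 and -0.30, and -0.31 with the mean of per-spot CPM. For the EMT transcription factors they were -0.56 with median-of-ratios scaling, -0.50 without those regions, -0.55 after thinning and -0.75 with the mean of per-spot CPM. The Ntn1 level, whole section, had -0.79 with the mean of per-spot CPM and -1.09 without those regions. The mesenchymal share differed by -25.8 points without keratin genes, -40.4 with genes weighted equally, -43.0 as the median over spots and -34.7 without those regions. The correlation of the epithelial and mesenchymal lists across spots, with unthinned CPM and with sums of z-scores, was 0.21 and 0.23 in the control and -0.77 and -0.48 in the NP137 section. The share with both Epcam and Vim differed by 44.1 points without thinning, 46.8 at 5414 UMIs and 0.72 for Krt14 and Vim. None of these changed sign; scaling and region choices moved values beyond counting error, and the cause was not tested.

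With a minimum of 200 counts the T cell value turned to -0.61, that of Cd4, which alone was left. The nerve median turned to -0.88, with Mbp, Prx and S100b left. Of the 181 values of 26 other lists, these 2 turned the sign of a result of at least 1.5-fold, as did 0 of the 632 values of 158 named genes; smaller results among them, such as the MHC class II median, also changed sign. No region was shared at resolution 1.0 or with 15 components; with at least 20 spots of both sections regions 7 and 9 qualified, with a mesenchymal median of -1.14. Depth limits low genes most, and region 9 of the NP137 section had a median of 510 UMIs per spot. No paired analysis was possible because each group had 1 section.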

Other observations

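The tests within spots of a high mesenchymal share and those of adjoining tissue, of endothelial and other tissue lists, of individual tumours, of macrophages, of H2-K1 and of haplotypes were chosen only after the results were seen. Spots with a mesenchymal share of at least 75% are a range of a score and not a cell type, and epithelial and mesenchymal levels within it are set in part by the bound. Among these 1278 control and 355 NP137 spots, Vim was at 3114 and 3041 CPM, Ntn1 at 115 and 79.7 CPM, and Unc5b at 129 and 68.2 CPM. The hypoxia list was lower in the NP137 spots, with a median log2 ratio of -0.94, below all 10000 random lists, and 10 of 14 members lower and 0 higher. Car9 was at 68.4 and 4.90 CPM, P4ha1 at 292 and 162 CPM and Egln3 at 116 and 64.5 CPM, although Egln3 was higher over the whole section.

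In the same spots macrophage, mast cell, fibroblast and endothelial lists were higher, with medians of 1.23 (9 of 13 members higher), 2.57 (7 of 7), 1.34 (7 of 12) and 0.61 (8 of 12). Skeletal muscle genes had a median of 3.45 (11 of 11) and smooth muscle and pericyte genes 1.34 (10 of 10), with Myh4 at 1.01 and 125 CPM, so muscle transcripts were among the counts of these NP137 spots. Keratinocyte differentiation genes (1.016, 13 of 16) and stress keratin genes (0.80, 6 of 9) were higher too, and the neutrophil list was level (-0.0048). The cell cycle list was at 0.064. Cd163 was at 13.8 and 70.5 CPM and Mcpt4 at 8.43 and 39.2 CPM. Collagen III (Col3a1) was at 1356 and 7373 CPM. The EMT transcription factor median was -0.15 there, against -0.61 over whole sections, with Snai1 at 296 and 173 CPM and Foxc2 at 53.5 and 9.35 CPM.

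The higher epithelial list in the NP137 section was weighed against skin beside the tumour, a smaller mesenchymal part and the choice of tumour. Without the spots of regions 5, 7, 9 and 11 the median was still 2.59, so these spots were not the whole source. Nearly all other NP137 spots lay in regions 3 and 4. Summed epithelial genes were at 33112 CPM in the NP137 spots of region 4 and 2939 CPM in region 3, against 3162 CPM in the control section. By this sum region 3 was not higher than the whole control section, and the rest lay mostly in region 4. Control regions 1, 2, 6 and 8 were at 3132, 1864, 3688 and 1562 CPM. The sum is weighted to abundant genes, so single genes can differ from it. Epcam was at 36.1 CPM in region 3 against 3.85 to 11.7 CPM in those control regions. Krt14 was at 780 CPM in region 3 and 992 CPM in the control section. Whether region 4, 5, 7 or 9 is tumour or skin beside it was not tested, so skin beside the tumour is not excluded. A smaller mesenchymal part would raise the other tissues alike, but their medians lay apart, at 0.28 for endothelial, 1.66 for neutrophil, 1.87 for mast cell and 1.97 for smooth muscle genes. Skeletal muscle and adipocyte genes were as high as the epithelial list or higher, at 2.998 and 4.31. The 2 sections may differ in each tissue's amount, which would spread the medians as well. This comparison therefore cannot decide whether a smaller mesenchymal part was the only source. Treatment and a difference between individual tumours cannot be told apart with 1 section per group, and the animals differed in sex as well. An effect of NP137 on tumour state therefore stays an untested hypothesis here.

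Osteoclast-associated genes were high in the control tumour, with Acp5 at 3824 CPM in region 1 and at 79.6 CPM in region 3 of the NP137 section. More macrophages in the control is not a sufficient explanation, since the macrophage list was higher in the NP137 section (median log2 ratio 0.58). The osteoblast and osteocyte genes, mostly Runx2, together reached 5.91% of the level of Acp5, below the limit set beforehand for bone. No bone sample gave a reference for that limit. Bglap (163 and 2 counts) and Ibsp (527 and 99 counts) were higher in the control. This comparison therefore cannot decide whether bone was a source. Of 14 further osteoclast genes, listed after Acp5 and its companions were seen, 10 were lower in the NP137 section, with a median of -1.58. Among them Oscar had 988 and 1, Ocstamp 1649 and 31, Dcstamp 1671 and 62, Siglec15 1307 and 43 and Calcr 290 and 4 counts, which is consistent with osteoclast-like giant cells in the control tumour, a hypothesis that the images not analysed here could test.

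H2-D1 had 1 count in the control and 3034 in the NP137 section. The class I partners B2m, Tap1, Tap2, Tapbp and Nlrc5 had a median log2 ratio of 0.78, which met the rule set beforehand for lower class I expression as a whole in the control; that reading was set aside on tests chosen afterwards, since H2-K1 was level at -0.063 and partners and class I genes moved both ways. Of 10 class I genes with at least 200 counts, 5 were at least 16-fold apart, 3 higher in the NP137 section (H2-D1, H2-Q6 and H2-Q7) and 2 higher in the control (H2-T22 with 844 and 0 counts, H2-T23 with 1710 and 8). A candidate explanation is that the animals carried different MHC haplotypes that the probes bind unequally, which these counts cannot decide because they led to it. If so, H2 genes, and other genes that vary between strains, say little about treatment; whether Tmpo, at 265 and 7.88 CPM, is such a gene was not tested.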
